A study of Homo sapiens with 9 samples.

How the data were processed

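RNA was measured in HT-29 cells, an established human colon adenocarcinoma line that grows as intestinal epithelium, on 9 one-colour (Cy3) Agilent whole human genome arrays. Per the labels, cells were grown with 10% serum, kept in 2% serum before exposure, and then left untreated or exposed for 24 h to 4 mg/ml of a bovine colostrum fraction or to 4 mg/ml of 3'-sialyllactose, a sialylated milk trisaccharide. The labels give 200 ng of RNA as the input of the labelling and describe the replicates as independent. The sample titles of the 3'-sialyllactose arrays use the wider term HMO, for human milk oligosaccharide, while their treatment labels name 3'-sialyllactose, and the treatment label was used here.

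The authors deposited 1 scanner file per array, written by Agilent Feature Extraction 10.7 (10.7.3.1 in the header). Per the file headers, its processed signal is an intensity in arbitrary units, corrected for background and for spatial and multiplicative trends within the array, with no scaling between arrays and with a surrogate value for spots near background. Probe positions are those of the file headers' genome build, hg19. The authors also deposited a value table of 42545 rows, whose values are on a natural log scale, as judged from their quartiles and maximum, with each column's median at 3.71. That table's columns share 1 distribution, so it had been quantile normalized. Values joined to the scanner files by probe name correlated with r between 0.0026 and 0.004, so its rows were scrambled against their names, and which row belongs to which probe stays unknown. The value table was therefore used only for counts and for the correlation between the treatments, and every named gene rests on the scanner files.

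Of 42405 probes, 34 were left out for outlier spots and 42371 were kept. The log2 processed signal of each array was reduced by the log2 of its 75th percentile. A probe was tested when it was well above background, by the scanner's own call, on all 3 arrays of at least 1 group, which held for 23684 probes. The brightest tested probe stood for its gene, which gave 19201 genes. Names came from a RefSeq table of GRCh38.p14, used for names only. Of the probes, 24910 matched by accession, 1868 by symbol and 587 by synonym, and 15040 matched nothing and kept the name in the scanner file. Of the genes tested, 13620 matched and 12877 were protein-coding.

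Differences were tested with limma 3.58.1 in R 4.3.3 (the files were read with the package data.table, version 1.17.8), with 1 fit of all 9 arrays, 6 residual degrees of freedom and 9.1 after moderation. The comparisons were colostrum fraction minus untreated, 3'-sialyllactose minus untreated, and colostrum fraction minus 3'-sialyllactose, all two-sided, with Benjamini-Hochberg adjustment over the 19201 genes and a threshold of 0.05. Every adjusted p given for a gene is limma's. Errors written after ± are limma's standard errors of a log2 difference between groups of n = 3. The number of arrays limits the precision. A gene whose lower group lay below background on every array is given a fold as a lower bound, "at least".

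The 38 gene lists covered glycan synthesis, mucins and junctions, inflammation, metabolism, stress, proliferation, differentiation, and markers of other cell types, of milk RNA and of RNA handling. Each had at least 5 measured members and was tested with limma's camera with a preset correlation of 0.01, adjusted over the 38 lists. The calls were repeated with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. The fits, thresholds, lists, alternatives and the rule for named genes were chosen before the data were examined, except slide as a block for the gene lists, which was added afterwards.

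By that rule the text names, per comparison, the 10 largest rises and 10 largest falls among called genes measured on all 9 arrays whose groups of 3 did not overlap. It adds up to 3 genes per direction whose lower group was below background, and the 4 members with the smallest p of each list that was called in any comparison or had at least 3 called members. Where fewer than 5 genes passed, the 10 with the smallest p are named as not passing. A list member named beyond these, most often to complete a count of 5 or fewer, was chosen after its values were seen, and the text says so where it is named.

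The scanner headers place the arrays on 2 slides. Slide 1 held untreated replicates 1 and 3, colostrum fraction replicate 2 and 3'-sialyllactose replicate 2, and slide 2 held the other 5 arrays, so each slide held all 3 groups. Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, no filter on dim probes, probes measured on all 9 arrays, the mean of a gene's probes, a fit of the 6 arrays compared, an intensity trend, array weights, slide or replicate number as a block, the deposited value table, a 1.5-fold minimum, and leaving out each array.

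The steps were tested on simulated data built on 19201 genes, with 50 changed genes at each fold size. For the colostrum fraction against untreated, 20 of 50 were recovered at 1.5-fold, 38 at 2-fold, 49 at 3-fold and 48 at 4-fold, and 12 unchanged genes were called. For 3'-sialyllactose against untreated, 11, 41, 49 and 49 of 50 were recovered at those sizes, and 12 unchanged genes were called. Each simulation changed 200 genes together, which eases the threshold that the Benjamini-Hochberg adjustment sets for each gene. Recovery would be lower with fewer changed genes, so these shares do not give the power of a comparison in which no gene passed. A list of 40 genes shifted by 0.5 on the log2 scale was called in both, with 0 of 37 unshifted lists called by camera. The simulated genes were drawn independently of each other, whereas the estimated correlation was 0.581 for the cell cycle list and 0.836 for the interferon list. The simulation therefore does not test camera's false calls for lists whose genes move together. Plots were drawn with matplotlib 3.10.9.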

Results

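Gene expression was measured in HT-29 cells on 9 arrays in 3 groups of 3: untreated cells, cells exposed to a bovine colostrum fraction at 4 mg/ml for 24 h, and cells exposed to 3'-sialyllactose at the same dose and time. Of the 42405 probes, between 57.2% and 58.3% were well above background in untreated cells. The range was 55.2% to 56.4% with the colostrum fraction and 54.6% to 57.0% with 3'-sialyllactose, and 0 probes were saturated on any array. Replicates of a group correlated across genes with r between 0.9886 and 0.9954, and the log2 difference between them had an SD between 0.274 and 0.436. On the first principal component, which held 33.3% of the variance, the colostrum fraction arrays lay between 22.7 and 33.7 and the other 6 arrays between -24.9 and -7.7. The second, which held 18.6%, spread the replicates within groups. It ran from -27.7 to 26.6 with 3'-sialyllactose, from -13.9 to 14.9 with the colostrum fraction and from -11.2 to 16.0 in untreated cells.

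The comparison of the colostrum fraction with untreated cells asked how the epithelial cells responded to it. Chemokines and an acute phase gene were among the genes with the largest rises. CCL20, a chemokine that attracts dendritic cells and lymphocytes, rose 32.0-fold (log2 5.00 ± 0.17, n = 3 per group, limma adjusted p = 7.65e-07), and CXCL1, a neutrophil chemokine, rose 25.3-fold (4.66 ± 0.11). The serum amyloid gene SAA1 was at least 28.6-fold higher, since its signal was below background in all 3 untreated arrays. Many genes of cell division fell. Among genes measured on all 9 arrays DHRS2, which encodes a short-chain dehydrogenase, fell most, to a level 3.93-fold lower (-1.98 ± 0.12, adjusted p = 3.43e-05).

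In all, 644 of 19201 genes (3.4%) passed, 330 higher and 314 lower, and 476 of them changed at least 1.5-fold, 231 higher and 245 lower. Of the 644, 557 were protein-coding and 71 had no match in the gene table. The groups did not overlap at 4212 genes (21.9%), where chance gives 10%.

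**Figure D1:**
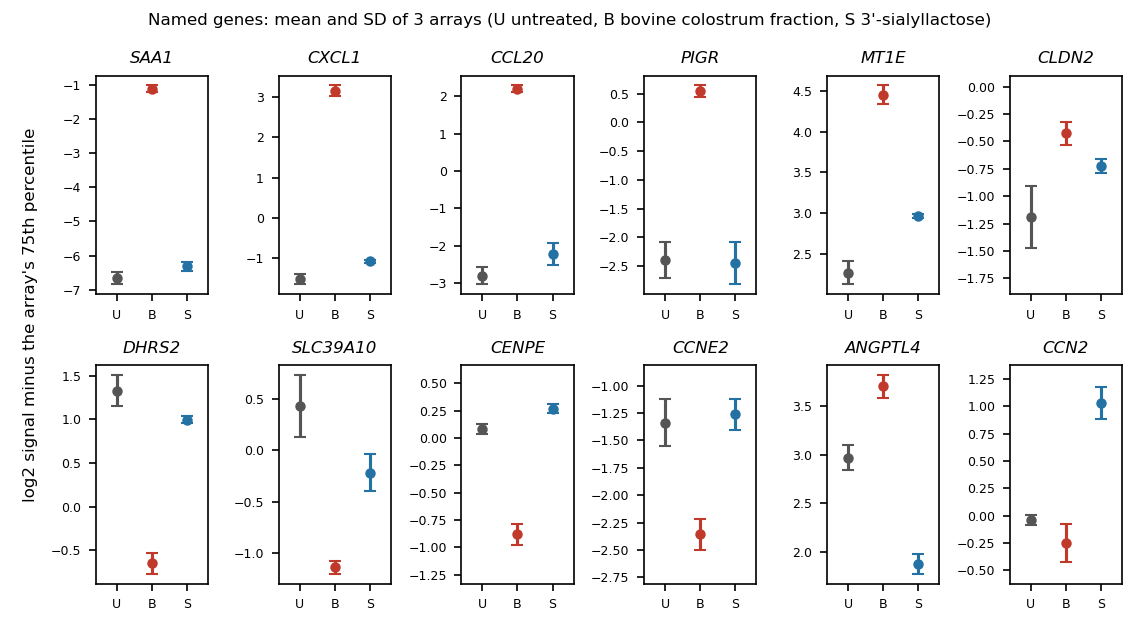
Mean and SD of 3 arrays for 12 named genes in untreated cells (U), with the bovine colostrum fraction (B) and with 3'-sialyllactose (S), as log2 signal minus the array's 75th percentile, each panel on its own scale. CCL20 stood at -2.81 in untreated cells, 2.19 with the colostrum fraction and -2.22 with 3'-sialyllactose, and ANGPTL4 at 2.97, 3.70 and 1.88.

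The remaining large rises among genes measured on all 9 arrays included an oxidase with its maturation factor, a chemokine and cytokines. DUOXA2 rose by 3.60 ± 0.19 and its partner DUOX2, a hydrogen peroxide-producing oxidase of the apical membrane, by 2.94 ± 0.12. IL4I1, a secreted amino acid oxidase, rose by 3.34 ± 0.17. The chemokine CXCL2 rose by 3.27 ± 0.13, the elastase inhibitor PI3 by 3.16 ± 0.10, and the cytokines IL32 and LTB by 3.06 ± 0.12 and 2.98 ± 0.18. PIGR, the receptor that carries IgA and IgM across the epithelium, rose 7.69-fold (2.94 ± 0.20). SAA2 was at least 19.4-fold and SPRR2A, a cornified envelope gene, at least 13.5-fold higher. The CXCL1 probe lies at chromosome 4, 74736850 to 74736909, and the PIGR probe at chromosome 1, 207101935 to 207101994, in hg19. The 2 probes of CXCL1 gave 3.81 and 4.66, and those of IL32 ranged from 2.11 to 3.06. SAA1 and SAA2 are close in sequence, as are CXCL1 and CXCL2, so their probes need not be fully specific.

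Targets of NF-kB, the transcription factor of the inflammatory response, rose as a group. Of 40 measured members of 49 listed, 30 rose and 1, TRAF1 (-0.66 ± 0.14), fell, and 33 rose and 1 fell when adjusted over the list alone. The list's median was 1.39 (camera adjusted p = 2.70e-56, and adjusted p = 0.000727 with an estimated correlation). IL17C, an epithelial cytokine, rose by 4.16 ± 0.13, although only 1 of its 3 untreated arrays was above background. Chosen after their values were seen, TNF rose by 2.88 ± 0.18, and the feedback inhibitors NFKBIA and TNFAIP3 by 1.29 ± 0.09 and 1.72 ± 0.15. TRAF1, itself an NF-kB target that encodes an adaptor of TNF receptors, was also chosen after its value was seen.

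**Figure D2:**
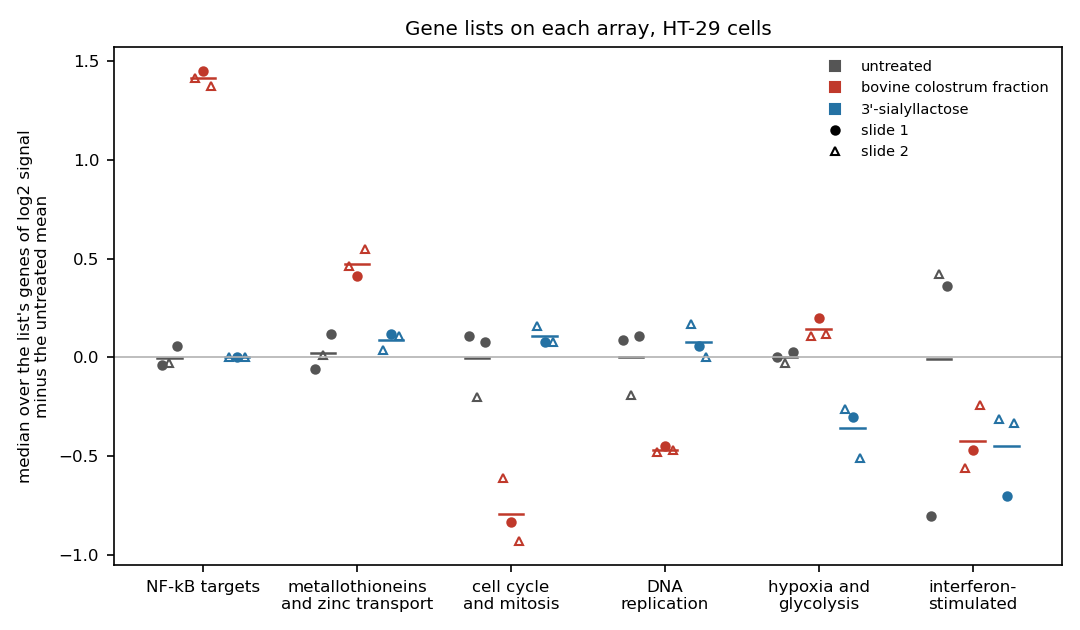
Median over the measured genes of each of 6 lists, per array, of the log2 signal minus the gene's untreated mean; symbols are single arrays by slide and bars are means of 3 arrays. NF-kB targets lay between 1.37 and 1.45 on the colostrum fraction arrays and at 0.00 on the 3'-sialyllactose arrays, while the interferon-stimulated genes of the untreated arrays spread from -0.80 to 0.42.

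Metallothioneins, which bind zinc and copper, rose. Of 22 measured members of the list of metallothioneins and zinc transporters, 10 rose and 2 fell, and 11 rose and 3 fell when adjusted over the list alone. MT1M rose 6.15-fold (2.62 ± 0.16), MT1E 4.52-fold (2.18 ± 0.11), MT1H by 1.74 ± 0.12 and MT1X by 1.70 ± 0.13. The 2 that fell encode zinc importers, SLC39A10 (-1.58 ± 0.16) and SLC39A4 (-0.76 ± 0.10), the latter chosen after its value was seen. The median was 0.47 (camera adjusted p = 5.14e-07, but adjusted p = 0.192 with an estimated correlation). The metallothionein genes are near-identical in parts, so their probes need not tell them apart.

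Genes of mitosis and, in smaller part, of DNA replication fell. Of 35 cell cycle and mitosis genes 25 fell, and 34 when adjusted over the list alone, with a median of -0.79. KIF23, a motor protein of cytokinesis, fell by 1.03 (SE 0.11), CENPE, a kinetochore motor, to -0.96 ± 0.09, NUSAP1 to -0.93 ± 0.12 and BUB1B to -0.86 ± 0.11. Of 42 DNA replication genes 12 fell, and 28 when adjusted over the list alone, with a median of -0.49. Among them were MCM10 (-1.09 ± 0.17), CCNE2 (-1.02 ± 0.14), ORC1 (-0.94 ± 0.15) and CDC45 (-0.83 ± 0.13). Camera gave adjusted p = 5.16e-37 for cell cycle and 4.84e-21 for replication, and adjusted p = 0.192 with an estimated correlation for each. Replication-dependent histones were not called: of 36 measured, 0 passed by limma, 2 were higher and 3 lower when adjusted over the list alone, and the median was 0.07.

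Other large falls were the following. SKA1, a kinetochore component, fell by 1.41 (SE 0.15), the repressor E2F8 by 1.38 (SE 0.24) and the spindle motor KIF15 by 1.26 (SE 0.17). CDKN2C, an inhibitor of CDK4 and CDK6, fell 2.83-fold, NEB fell by 1.67 (SE 0.11), the protease gene KLK12 by 1.42 (SE 0.11), GPR19 by 1.33 (SE 0.25) and NEURL1B by 1.24 (SE 0.10), although the other probe of NEURL1B gave -0.01. ANO3 was at least 3.32-fold, WDR76 at least 3.29-fold and CMAHP at least 3.1-fold lower, each below background on the colostrum fraction arrays.

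Early response genes of growth factor signalling through ERK had a higher median with the colostrum fraction, but few passed singly. Of 34 measured, 5 rose, and 14 when adjusted over the list alone: DUSP5 (0.90 ± 0.09), DUSP1 (0.68 ± 0.10), PHLDA2 (0.54 ± 0.10), IER3 (0.51 ± 0.09) and LIF (0.55 ± 0.12), LIF having been chosen after its value was seen. The first pair encode phosphatases of MAP kinases. The median was 0.28 (camera adjusted p = 1.93e-07, and adjusted p = 0.137 with an estimated correlation). Among hypoxia and glycolysis genes 4 of 36 rose, and 5 when adjusted over the list alone: ANGPTL4 (0.74 ± 0.11), EGLN3 (0.59 ± 0.11), ERO1A (0.56 ± 0.12) and P4HA2 (0.43 ± 0.09). Their median was 0.14 (camera adjusted p = 0.000107, and adjusted p = 0.443 with an estimated correlation).

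Barrier genes moved in both directions. Among 28 mucins and goblet cell products, the membrane mucin MUC1 rose by 0.70 ± 0.10, while the goblet cell peptide TFF3 (-0.68 ± 0.12) and the lectin REG4 (-0.92 ± 0.17) fell. Adjusted over the list alone, 1 rose and 3 fell, and the median was -0.17 (camera adjusted p = 0.0126, and adjusted p = 0.192 with an estimated correlation). SPINK4, a goblet cell product below background on all colostrum fraction arrays, did not pass (adjusted p = 0.0542). Of 27 junction components 1 rose, CLDN2, which forms cation pores (0.77 ± 0.14), as it did when adjusted over the list alone, and the median was 0.14 (camera adjusted p = 0.00574, and adjusted p = 0.426 with an estimated correlation). Of 35 adhesion genes 4 rose, and 5 when adjusted over the list alone: ICAM1, a leukocyte ligand (1.12 ± 0.09), the galectin LGALS2 (0.83 ± 0.10), the complement regulator CD55 (0.56 ± 0.10) and CEACAM1 (0.45 ± 0.10). Their median was 0.16 (camera adjusted p = 5.49e-05, and adjusted p = 0.349 with an estimated correlation).

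Interferon-stimulated genes had a lower median with the colostrum fraction, at -0.43, but 0 of 39 passed by limma, with 0 also when adjusted over the list alone. Camera called the list (adjusted p = 2.08e-05), but it gave adjusted p = 0.596 with an estimated correlation, and fry gave adjusted p = 0.417. The untreated arrays differed among themselves, with list medians of -0.80, 0.42 and 0.36, so that 1 untreated array lay below all 6 treated arrays. Without untreated replicate 2 the camera adjusted p was 0.0425. IFIT2 stood at -0.93 ± 0.29 and USP18 at -0.85 ± 0.27, neither passing.

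Gene groups of basal metabolism shifted little. Among 59 cytosolic ribosomal protein genes 0 passed by limma, and 0 when adjusted over the list alone. Their median was 0.12 (camera adjusted p = 0.000106, and adjusted p = 0.548 with an estimated correlation), and it turned to -0.03 with quantile normalization. Among 51 nuclear genes of oxidative phosphorylation 0 passed by limma, and 0 when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.000107, and adjusted p = 0.517 with an estimated correlation).

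Markers of other cells and of RNA handling gave the following. Of 13 measured leukocyte markers 1 rose, the integrin ITGAM (0.84 ± 0.13), with 1 when adjusted over the list alone. The median was 0.21 (camera adjusted p = 0.0371, and adjusted p = 0.544 with an estimated correlation), and the call ended with slide as a block (adjusted p = 0.0508). Of 7 measured fibroblast and smooth muscle markers 1 fell, VIM (-0.71 ± 0.16), and 3 when adjusted over the list alone. The median was -0.38 (camera adjusted p = 0.0126, and adjusted p = 0.192 with an estimated correlation), although normexp background correction turned it to 0.02. It ranged from -0.58 to -0.14 with 1 array left out. Of 11 measured milk and mammary gland transcripts 2 rose, PIGR and XDH (0.73 ± 0.10), as they did when adjusted over the list alone, and the median was 0.25 (camera adjusted p = 0.0126, and adjusted p = 0.192 with an estimated correlation). Both of these genes are also expressed by intestinal epithelium. Of 9 measured enteroendocrine markers 0 passed by limma or when adjusted over the list alone (median -0.03). Of 7 Paneth and tuft cell markers 1 rose, the protease MMP7 (1.30 ± 0.13), with 1 when adjusted over the list alone (median 0.02). Of 14 RNAs that report on RNA handling 1 fell, SNHG1 (-0.49 ± 0.10, chosen after its value was seen), with 1 when adjusted over the list alone (median -0.06). Over all 19201 genes 2937 had an unadjusted p under 0.05.

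Camera called 18 of 38 lists, 13 up and 5 down, and of these the NF-kB list alone held with an estimated correlation. With quantile normalization it called 12, without junction components, antigen presentation, TGF-beta and BMP responses, ribosomal proteins, oxidative phosphorylation and fibroblast markers. Some medians lay nearer 0 there, from 0.18 to 0.06 for antigen presentation, 0.14 to 0.05 for oxidative phosphorylation, 0.16 to 0.07 for adhesion genes and 0.14 to 0.07 for hypoxia and glycolysis, while others lay further from it, from -0.43 to -0.50 for interferon-stimulated genes and -0.17 to -0.22 for mucins. Within slide 1 and slide 2 the NF-kB median was 1.42 and 1.44, the metallothionein median 0.40 and 0.53, the cell cycle median -0.92 and -0.61 and the DNA replication median -0.58 and -0.36. With slide as a block 491 genes passed, 464 of them among the 644, and leaving out untreated replicate 1 gave 294, untreated replicate 3 304, colostrum fraction replicates 1, 2 and 3 426, 376 and 347.

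For 3'-sialyllactose the question was the same, and no gene passed. The genes with the smallest p had lower values for hypoxia-responsive genes and higher values for a few growth and metal response genes. ANGPTL4, a secreted lipoprotein lipase inhibitor induced by hypoxia and PPAR, stood at -1.09 ± 0.11 (adjusted p = 0.0594, 95% interval -1.34 to -0.84), and the vasodilator peptide gene ADM at -1.05 ± 0.12. CCN2, a matricellular gene induced by YAP and TGF-beta, stood at 1.07 ± 0.12. None of these passed the threshold.

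The others of the 10 genes with the smallest p, none of which passed, were EDN2 (-0.76 ± 0.09), PNCK (-0.95 ± 0.11), the glycolytic regulator PFKFB4 (-0.97 ± 0.13), P4HA2 (-0.63 ± 0.09), SLC6A8 (-0.76 ± 0.12), MT1E (0.70 ± 0.11) and MT1M (1.0 ± 0.16). Their adjusted p ranged up to 0.232. By limma 0 of 19201 genes passed, with 1249 at an unadjusted p under 0.05, and the groups did not overlap at 2451 genes (12.8%), where chance gives 10%. Calls appeared with normexp background correction (4 genes: ANGPTL4, ADM, CCN2 and PFKFB4), with probes measured on all 9 arrays (5: ANGPTL4, CCN2, ADM, EDN2 and PNCK), with an intensity trend (9) and with array weights (16).

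The hypoxia and glycolysis genes had a median of -0.31 with 3'-sialyllactose, and 33 of 36 were negative. Over all genes 0 passed by limma, whereas 18 were lower when adjusted over the list alone. Camera called the list (adjusted p = 4.14e-23), fry gave adjusted p = 0.0105, and it was adjusted p = 0.131 with an estimated correlation. The median was -0.31 within slide 1 and within slide 2. Besides the genes above, HK2, the first enzyme of glycolysis, stood at -0.55 ± 0.10 and ENO2 at -0.66 ± 0.12, the 2 chosen after their values were seen.

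Early ERK response genes had a median of 0.16 (camera adjusted p = 3.96e-08, fry adjusted p = 0.0399, and adjusted p = 0.131 with an estimated correlation), and 7 were higher when adjusted over the list alone. Among them HBEGF, an EGF receptor ligand, stood at 0.83 ± 0.19 and DUSP5 at 0.51 ± 0.09, neither passing over all genes. The interferon-stimulated list had a median of -0.47 (camera adjusted p = 2.77e-07, and adjusted p = 0.844 with an estimated correlation), and its call ended without untreated replicate 2, at 0.0602. Metallothioneins and zinc transporters had a median of 0.06 (adjusted p = 0.00174, and adjusted p = 0.661 with an estimated correlation), with 5 higher and 3 lower when adjusted over the list alone. Mucins and goblet cell products had a median of -0.12 (0.019, and adjusted p = 0.429 with an estimated correlation), with 4 lower when adjusted over the list alone, among them MUC5B at -0.61 ± 0.14 and TFF1 at -0.44 ± 0.10.

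Camera's other calls with 3'-sialyllactose were small shifts with 0 members past limma's threshold and 0 when adjusted over the list alone, and none held with an estimated correlation. The medians were 0.10 for Wnt targets and stem cell markers (adjusted p = 0.436 with an estimated correlation), 0.10 for cell cycle and 0.09 for DNA replication (0.844 for each), 0.05 for histones (0.844), 0.08 for NRF2 targets (0.758), 0.05 for p53 targets (0.535) and -0.26 for Paneth and tuft cell markers (0.436), whose call also ended with slide as a block (adjusted p = 0.135). The cell cycle median was -0.04 within slide 1 and 0.31 within slide 2. NF-kB targets had a median of -0.04 (camera adjusted p = 0.414), with CXCL1 at 0.44 ± 0.11 and DUOX2 at -0.66 ± 0.12, neither passing. In all, camera called 12 of 38 lists, 8 up and 4 down, fry called 2, and 0 held with an estimated correlation. Without untreated replicate 2 camera called 3 and without 3'-sialyllactose replicate 1 it called 5. With slide as a block 0 genes passed, with 1366 at an unadjusted p under 0.05, and without 3'-sialyllactose replicate 2 there were 2.

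Set directly against 3'-sialyllactose at the same dose and time, the colostrum fraction gave higher inflammatory and hypoxia-responsive genes and lower genes of cell division. CCL20 was 21.3-fold higher with the colostrum fraction (4.41 ± 0.17, limma adjusted p = 1.62e-06), DUOXA2 19.2-fold (4.26 ± 0.19) and CXCL1 18.7-fold (4.22 ± 0.11). ANGPTL4 was 3.54-fold higher (1.83 ± 0.11) and CCN2 2.43-fold lower (-1.28 ± 0.12). In all, 1326 genes (6.9%) passed, 742 higher and 584 lower with the colostrum fraction, and 843 of them at least 1.5-fold, 416 higher and 427 lower. With quantile normalization 588 were higher and 642 lower, so the balance of directions depended on the scaling. The groups did not overlap at 4938 genes (25.7%), where chance gives 10%.

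Further large differences in the same direction were DUOX2 (3.60 ± 0.12), IL4I1 (3.59 ± 0.17), PI3 (3.38 ± 0.10), PIGR (3.0 ± 0.20), IL32 (2.90 ± 0.12), CXCL2 (2.78 ± 0.13) and LTB (2.69 ± 0.18). SAA1 was at least 23.7-fold, IL17C at least 21.3-fold and the complement gene C3 at least 20.9-fold higher. Of the 40 NF-kB targets 29 were higher, and 35 higher and 1 lower when adjusted over the list alone, with a median of 1.34 (camera adjusted p = 1.64e-42, and adjusted p = 0.00165 with an estimated correlation). Of the metallothionein and zinc list 11 were higher and 3 lower, and 12 and 3 when adjusted over the list alone, with a median of 0.48 (camera adjusted p = 0.000218, and adjusted p = 0.396 with an estimated correlation). The 3 lower were the importers SLC39A10 (-0.92 ± 0.16), SLC39A8 (-0.67 ± 0.15) and SLC39A4 (-0.45 ± 0.10), chosen after their values were seen.

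Among lower genes measured on all 9 arrays NEB (-1.88 ± 0.11), DHRS2 (-1.65 ± 0.12) and E2F8 (-1.59 ± 0.24) differed most, followed by GPR19 (-1.55 ± 0.25), HEPACAM2 (-1.46 ± 0.17), the cohesion genes DSCC1 (-1.44 ± 0.13) and ESCO2 (-1.41 ± 0.23), the ribonucleotide reductase subunit RRM2 (-1.44 ± 0.30), KIF15 (-1.39 ± 0.17) and CDKN2C (-1.39 ± 0.14). SPINK4 was at least 3.54-fold, NAT8 at least 3.37-fold and ANO3 at least 3.29-fold lower. Of 35 cell cycle genes 31 were lower, and 35 when adjusted over the list alone, with a median of -0.90 and CENPE at -1.15 ± 0.09. Of 42 replication genes 25 were lower, and 32 when adjusted over the list alone, with a median of -0.60. Camera gave adjusted p = 1.14e-36 and 2.50e-23 for these lists, and adjusted p = 0.168 with an estimated correlation for each. Of 36 histones 2 were lower, H1-5 (-1.17 ± 0.20) and H2AX (-0.92 ± 0.17), and 2 when adjusted over the list alone.

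Hypoxia and glycolysis genes separated the treatments. Of 36, 19 were higher with the colostrum fraction than with 3'-sialyllactose, and 28 when adjusted over the list alone, with a median of 0.54 (camera adjusted p = 3.78e-17, and adjusted p = 0.168 with an estimated correlation). The prolyl hydroxylase EGLN3 was higher by 1.13 ± 0.11, P4HA2 by 1.06 ± 0.09 and HK2 by 0.84 ± 0.10. The within-slide medians were 0.56 and 0.54. The TGF-beta and BMP list was not called (median 0.15, camera adjusted p = 0.341). Of its members 4 were higher with the colostrum fraction and 4 lower, and 9 and 4 when adjusted over the list alone. Among the higher were BMP2 (0.85 ± 0.11), BHLHE40 (0.52 ± 0.10) and SMAD6 (0.41 ± 0.09). Lower were CCN2, BAMBI (-0.49 ± 0.12), ID3 (-0.45 ± 0.11) and CCN1 (-0.45 ± 0.11). Of these, SMAD6, BAMBI, ID3 and CCN1 were chosen after their values were seen.

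A few barrier genes differed as well. Not passing were 24 of 28 mucins and goblet cell products, 25 of 27 junction components and 27 of 35 adhesion genes. Camera did not call the mucin list (adjusted p = 0.395). It called junction components (adjusted p = 0.012) and adhesion genes (3.05e-05), with adjusted p = 0.489 and 0.396 with an estimated correlation. MUC1 (1.05 ± 0.10), the trefoil peptide TFF2 (0.73 ± 0.11) and the secreted mucin MUC2 (0.54 ± 0.14) were higher with the colostrum fraction, while SPINK4 was lower, and 4 were higher and 3 lower when adjusted over the list alone. Of the junction components F11R was higher (0.46 ± 0.09) and CLDN1 lower (-0.72 ± 0.17), with 4 higher and 1 lower when adjusted over the list alone. Of the adhesion genes 8 were higher, and 11 when adjusted over the list alone, led by ICAM1 (1.22 ± 0.09), CEACAM1 (0.75 ± 0.10), CD55 (0.72 ± 0.10) and LGALS2 (0.74 ± 0.10).

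Camera called 16 of 38 lists, 12 up and 4 down, fry called 18, and of camera's calls the NF-kB list alone held with an estimated correlation. With slide as a block 1273 genes passed, 1184 of them among the 1326. Without 3'-sialyllactose replicates 2 and 3 the counts were 625 and 824, and without colostrum fraction replicates 1, 2 and 3 they were 880, 817 and 689.

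Because 3'-sialyllactose is a sialylated sugar and glycans line the epithelium, the enzymes that build and trim glycans were followed in each comparison. With 3'-sialyllactose 0 of 23 genes of sialic acid metabolism passed by limma (median 0.03, camera adjusted p = 0.799), and 1 was lower when adjusted over the list alone. With the colostrum fraction GNE, which starts sialic acid synthesis, rose by 0.69 ± 0.10 and ST3GAL5, the ganglioside GM3 synthase, by 0.91 ± 0.15, with 4 higher and 1 lower when adjusted over the list alone (median 0.09, camera adjusted p = 0.172). Directly compared, 5 were higher with the colostrum fraction and 2 lower, and 10 and 5 when adjusted over the list alone. Higher were ST8SIA6 (1.18 ± 0.14), ST3GAL5 (0.98 ± 0.15), GNE (0.49 ± 0.10), ST3GAL4 (0.74 ± 0.17) and the sialidase NEU1 (0.40 ± 0.09). Lower were ST6GAL1 (-0.90 ± 0.13) and ST6GALNAC1 (-0.51 ± 0.12). ST3GAL4, NEU1 and ST6GALNAC1 were chosen after their values were seen, and camera did not call the list (adjusted p = 0.341).

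Other glycan enzymes changed in few members, all of them chosen after their values were seen. Of the 25 genes listed as O-glycan enzymes 1 rose with the colostrum fraction, B3GNT5 (0.67 ± 0.08), and 2 when adjusted over the list alone. B3GNT5 starts lacto-series glycolipids, so its rise is not that of an O-glycan enzyme. The list's median was 0.14 (camera adjusted p = 0.0647, and adjusted p = 0.517 with an estimated correlation), and with slide as a block it was called (adjusted p = 0.0225). Directly compared with 3'-sialyllactose B3GNT5 (0.66 ± 0.08) and B3GNT3 (0.53 ± 0.10) were higher. Of 34 N-glycan enzymes the galactosyltransferase B4GALT5 rose (0.41 ± 0.09), with 1 higher and 1 lower when adjusted over the list alone (median 0.03), and against 3'-sialyllactose B4GALT5 was higher (0.58 ± 0.09) and MGAT4A lower (-0.54 ± 0.13). Of 18 fucosylation genes 0 passed by limma with either treatment (median 0.00 with the colostrum fraction and -0.05 with 3'-sialyllactose), with 0 and 1 when adjusted over the list alone. Between the treatments POFUT4 (0.71 ± 0.11) and the Lewis fucosyltransferase FUT3 (0.40 ± 0.09) were higher with the colostrum fraction.

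**Figure D3:**
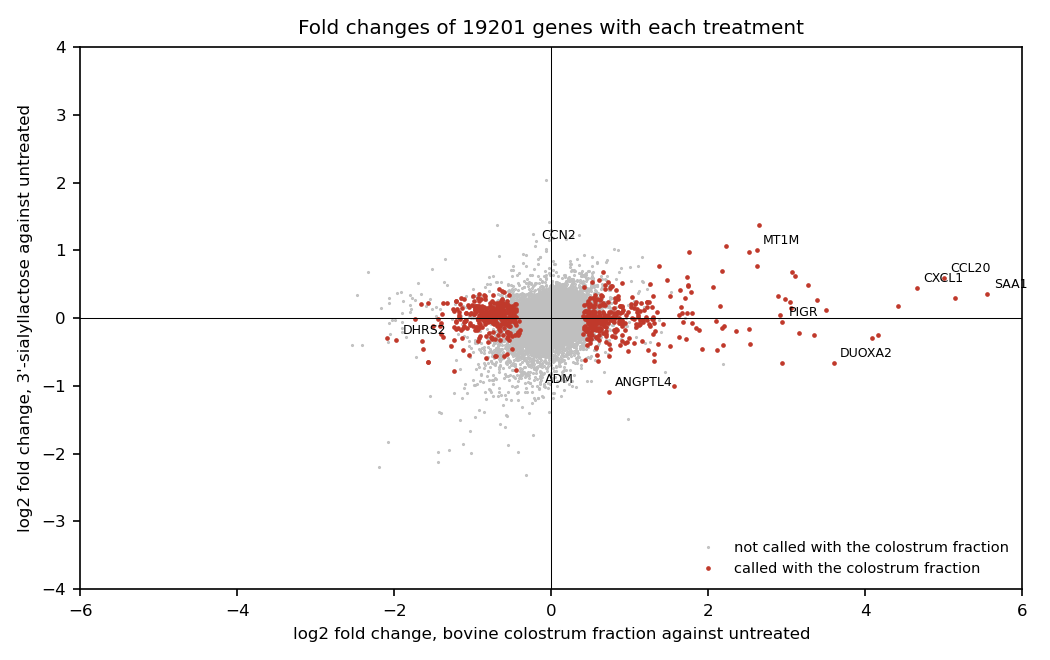
Log2 fold change of each of 19201 genes with the bovine colostrum fraction (x axis) and with 3'-sialyllactose (y axis), both against the same 3 untreated arrays; red points passed the test with the colostrum fraction. CCL20 lay at 5.00 on the x axis and 0.58 on the y axis, CXCL1 at 4.66 and 0.44, and ANGPTL4 at 0.74 and -1.09.

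Whether the treatments moved the same genes was asked across all genes. The correlation of their fold changes was r = 0.193 (Spearman's rho 0.167), across genes, which are not independent replicates. Because both fold changes share the untreated arrays, 1000 simulations of unchanged groups gave a mean r of 0.50 (0.465 to 0.53), above the r observed. The colostrum fraction did change genes, which lowers r by itself, so this gap does not show whether the same genes moved. Of the 644 genes called with the colostrum fraction, 291 (45.2%) had the same sign with 3'-sialyllactose. Their median 3'-sialyllactose change in the colostrum fraction's direction was -0.025. The observed covariance was 0.0144 against 0.0174 simulated, a difference of -0.003. The metallothioneins MT1E and MT1M had the same sign with both treatments and remained higher with the colostrum fraction (1.48 ± 0.11 and 1.62 ± 0.16).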

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

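Except for the difference of the milk genes and the counts of other splits, the tests in this part, with the level of the milk genes, were chosen only after the result was seen. In 12 gene lists the treatments' medians against untreated cells had opposite signs and camera called the direct difference between them. The median differences, colostrum fraction minus 3'-sialyllactose, were 1.34 for NF-kB targets, -0.90 for cell cycle and mitosis, -0.60 for DNA replication and 0.54 for hypoxia and glycolysis. They were 0.33 for antigen presentation, 0.29 for Paneth and tuft cell markers, 0.22 for junction components, 0.19 for milk and mammary gland transcripts, 0.19 for adhesion genes, -0.19 for p53 targets, 0.14 for oxidative phosphorylation and 0.13 for Toll-like and NOD-like receptor signalling. The direct differences kept their sign with each array left out, which says little because the lists were picked by these same differences. In 8 lists a median against untreated cells near 0 turned, so the opposite signs there rest on little. With 3'-sialyllactose these medians ranged from -0.02 to 0.15 for cell cycle, -0.02 to 0.16 for DNA replication, -0.05 to 0.01 for NF-kB targets, -0.08 to 0.01 for adhesion genes and for oxidative phosphorylation, and -0.06 to 0.02 for milk transcripts. With the colostrum fraction they ranged from -0.12 to 0.12 for Paneth and tuft cell markers and from -0.11 to 0.01 for p53 targets. With an estimated correlation the NF-kB difference held (adjusted p = 0.00165), and those of the other 11 ranged from adjusted p = 0.168 to 0.664.

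The rise of inflammatory and metal-binding genes with the colostrum fraction may be a response of the cells, a carry-over of bovine material, or an array effect. A difference between slides is argued against as the whole cause by 248 of the 330 higher genes still being called higher with slide as a block. A carry-over of leukocytes is not settled, and human probes need not bind bovine transcripts. The median over 13 leukocyte markers was 0.21, 9 were positive, ITGAM rose (0.84 ± 0.13) and CD68 stood at -0.01 ± 0.10. The list's median lay between 0.13 and 0.28 on the colostrum fraction arrays and between -0.14 and 0.06 on the untreated arrays. That shift is small but in the direction a carry-over would give. It was uneven between slides, with a median difference from untreated of 0.36 within slide 1 and 0.02 within slide 2. Of the 24 leukocyte markers listed, those not among the 13 were not measured above background. Within the same limit, none of the casein and whey genes CSN1S1, CSN2, CSN3, LALBA and LTF was above background on any array. Their mean log2 levels with the colostrum fraction, -5.51 to -6.71, lay below the dimmest of the 330 higher genes (-4.49). That order was set by the filter, since a tested gene had to be above background in at least 1 group. The median difference of these milk genes, 0.11, compares background values, so RNA of milk stays undecided as a source. A response of the cells stays open as a hypothesis, as does whether a protein, a lipid, a metal or a microbial trace such as endotoxin in the fraction set it off, which no array here tests.

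Hypoxia and glycolysis genes lay lower with 3'-sialyllactose than with the colostrum fraction. Each treatment had 1 array on slide 1 and 2 on slide 2, so a shift common to a slide cancels in this comparison. The within-slide medians, the smaller of which was 0.54, therefore add no test of such a shift. A single deviant array is argued against by the leave-one-out medians, the lowest of which was 0.45. Differences in cell density, medium depth or time out of the incubator between cultures could give the same pattern and were not measured. An effect of the sugar itself also stays open.

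Interferon-stimulated genes lay lower with both treatments. Both medians were taken against the same 3 untreated arrays, so they are not independent observations. The direct difference between the treatments had a median of -0.03. A spread between cultures that does not follow treatment is a candidate explanation, since 1 untreated array had a list median below all 6 treated arrays. The pair of untreated arrays on slide 1 differed by 1.16, which shows a spread within a slide but does not test slides as the cause. Within slides 1 and 2 the medians were -0.31 and -0.92 with the colostrum fraction and -0.44 and -0.79 with 3'-sialyllactose. The lower median was thus seen within each slide, although 1 of the groups compared had 1 array there. An effect of both treatments stays open, but the leave-one-out medians ranged from -0.81 to -0.19 with the colostrum fraction and from -0.87 to -0.23 with 3'-sialyllactose, in both cases lowest without untreated replicate 1.

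Other splits of the arrays were too few for a share under 0.05. For the colostrum fraction against untreated the real split gave 644 genes and the highest of the other splits 0, so 1 of 10 splits gave as many. For the colostrum fraction against 3'-sialyllactose the real split gave 1326 and the highest other 0, again 1 of 10. For 3'-sialyllactose against untreated all 10 splits gave 0 by limma, where the real split had 1249 genes at an unadjusted p under 0.05.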

How the results depend on the processing

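Slide as a block for the gene lists was the alternative chosen only after the result was seen. Counts in the deposited value table are of its 42545 rows, not of genes, with no filter on dim probes. The count of 644 genes for the colostrum fraction against untreated was 343 without a filter on dim probes, where 34005 genes were tested, 1485 with array weights and 994 in the deposited value table, and it lay between 447 and 756 with quantile normalization, median centring, normexp, probes on all 9 arrays, mean probes, the 6 arrays compared, an intensity trend, slide as a block and the 1.5-fold minimum. Leaving out 1 array gave 294 (without untreated replicate 1) to 617, with 304 without untreated replicate 3 and 426, 376 and 347 without colostrum fraction replicates 1, 2 and 3. The 0 genes by limma for 3'-sialyllactose became 4 with normexp, 5 with probes on all 9 arrays, where 17550 genes were tested, 9 with a trend, 16 with array weights and 12 in the value table, and 0 to 2 with 1 array left out (2 without 3'-sialyllactose replicate 2). The 1326 genes between the treatments became 664 without a filter, 726 with the 6 arrays compared, where fewer arrays estimate the spread, and 843 with the 1.5-fold minimum, and otherwise, apart from the replicate block, lay between 1062 and 1822. With 1 array left out they were 625 (without 3'-sialyllactose replicate 2) to 1204, with 824 without 3'-sialyllactose replicate 3 and 880, 817 and 689 without colostrum fraction replicates 1, 2 and 3. The correlation of 0.193 became 0.41 without a filter, 0.126 with probes on all 9 arrays and 0.317 in the value table, and 0.1 (without 3'-sialyllactose replicate 1) to 0.305 (without untreated replicate 3) with 1 array left out, where untreated replicate 2 gave 0.285 and colostrum fraction replicate 1 0.125. Camera's 18, 12 and 16 lists fell to 1, 0 and 1 with an estimated correlation, and fry called 15, 2 and 18. With 1 array left out they were 16 to 19, 3 to 13 and 11 to 16, with 3 of the 12 without untreated replicate 2 and 5 without 3'-sialyllactose replicate 1. Except where fewer or more genes or arrays were used, the cause was not tested. Replicate numbers gave no sign of pairing the arrays. Deviations of the same number correlated from -0.37 to 0.15 (median -0.17) and those of other numbers from -0.35 to 0.39 (median 0.05). With 3 arrays per group these correlations cannot exclude a pairing. With the replicate block the counts were 367, 0 and 723, where the block takes residual degrees of freedom, and the lists 17, 12 and 15. For the named genes, 1425 of 1653 values for the colostrum fraction against untreated and 1754 of 2052 between the treatments stayed past the threshold, 228 and 298 fell short of it, and 0 reversed. For the 10 genes named with 3'-sialyllactose, 27 of 200 values passed and 0 reversed. Of the 42371 probes kept, 21612 were measured on all 9 arrays, and whether signal near background limited the rest was not tested.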

Other observations

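The test on zinc and the join to the value table were chosen only after the result was seen. Receptors of innate immunity changed in few members with the colostrum fraction: of 22 measured genes of Toll-like and NOD-like receptor signalling, TLR4, the endotoxin receptor (1.17 ± 0.14), the kinase IRAK2 (1.31 ± 0.15) and the adaptor TICAM1 (0.49 ± 0.09) rose, with 4 higher and 1 lower when adjusted over the list alone (median 0.11, camera adjusted p = 0.081). Against 3'-sialyllactose the same 3 were higher, at 1.22 ± 0.14, 1.38 ± 0.15 and 0.47 ± 0.09. Of 23 antigen presentation genes the immunoproteasome subunit PSMB10 rose (0.67 ± 0.14), with 4 when adjusted over the list alone (median 0.18, camera adjusted p = 0.00486, and adjusted p = 0.517 with an estimated correlation). PSMB10 (0.89 ± 0.14), ERAP2 (0.42 ± 0.10), TAPBP (0.46 ± 0.11) and ERAP1 (0.50 ± 0.12) were higher than with 3'-sialyllactose. The lipocalin LCN2, which binds bacterial siderophores, rose by 1.68 ± 0.10, the 1 of 19 iron genes to pass, with 1 when adjusted over the list alone (median 0.03), and was chosen after its value was seen.

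Xenobiotic and oxidative stress genes rose in a few members. TIPARP, a feedback inhibitor of the aryl hydrocarbon receptor (0.80 ± 0.10), CYP1B1 (1.01 ± 0.14) and UGT1A6 (0.47 ± 0.10) rose among 17 AhR and xenobiotic genes, with 3 higher and 3 lower when adjusted over the list alone (median 0.12, camera adjusted p = 0.113). GPX2, a gut glutathione peroxidase, rose by 0.92 ± 0.13 and UGT1A6 with it among 29 NRF2 targets, with 7 when adjusted over the list alone (median 0.21, camera adjusted p = 0.000285, and adjusted p = 0.314 with an estimated correlation). Among 29 enterocyte genes KRT20 (0.42 ± 0.09) and CEACAM1 (0.45 ± 0.10) rose, while the brush border enzymes ANPEP (-0.75 ± 0.12) and SI (-0.80 ± 0.18) and the receptor GUCY2C (-0.84 ± 0.14) fell, as they did when adjusted over the list alone (median 0.08), SI having been chosen after its value was seen.

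Regulators of growth and stress moved singly with the colostrum fraction. Among 22 Wnt and stem cell genes NKD2 (0.72 ± 0.12) and SOX9 (0.49 ± 0.09) rose and DKK1 fell (-0.84 ± 0.17), with 2 higher and 2 lower when adjusted over the list alone (median 0.00). Of 28 TGF-beta and BMP genes 2 rose, among them the BMP target ID1 (0.54 ± 0.10). Adjusted over the list alone, 4 were higher and 2 lower. The median was 0.15 (camera adjusted p = 0.0471, and adjusted p = 0.425 with an estimated correlation). That call held in 4 of 9 fits with 1 array left out, where the median of these TGF-beta and BMP genes ranged from 0.05 to 0.21. PLK3 (0.85 ± 0.12) and PLK2 (0.49 ± 0.11) rose among 26 p53 targets, with 3 higher and 4 lower when adjusted over the list alone (median -0.07). CEBPB (0.55 ± 0.08) and ATF5 (0.56 ± 0.09) rose and DDIT3 fell (-0.83 ± 0.13) among 35 ATF4 targets, with 4 higher and 3 lower when adjusted over the list alone (median -0.05). ANGPTL4 and the fat cell regulator PPARG (0.69 ± 0.14) rose among 22 fatty acid oxidation and PPAR genes, with 4 when adjusted over the list alone (median 0.04). By limma 0 genes passed among 25 of cholesterol synthesis (median 0.01), 16 of fatty acid synthesis (0.00), 26 of the unfolded protein response (0.03) and 24 cytosolic heat shock proteins (0.10, camera adjusted p = 0.0663, adjusted p = 0.476 with an estimated correlation, and 0.0275 with slide as a block). Adjusted over the list alone, fatty acid synthesis had 2 higher and 2 lower and the others 0, and 2937 of 19201 genes had an unadjusted p under 0.05.

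One hypothesis is that the colostrum fraction brought zinc to the cells, which could raise metallothioneins. SLC30A1, the zinc exporter induced by zinc, stood at 0.43 ± 0.12 against untreated cells (limma adjusted p = 0.109), which leaves the question undecided, and it was higher than with 3'-sialyllactose (0.50 ± 0.12). Metallothioneins also respond to copper and to inflammatory signals, which were not separated here.

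In the deposited value table the 36 correlations between pairs of arrays followed those of the scanner files with r = 0.969, so its columns held these arrays while its rows could not be named.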
